A study of Mus musculus with 4 samples.

How the data were processed

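RNA-seq was done on Mnk3 cells, with 2 libraries of untreated cells and 2 of cells stimulated with IL-1b and IL-23 at 10 ng/ml each for about 16 h. Per the labels' protocols, total RNA was prepared with a Qiagen kit and ribosomal RNA was depleted. STAR, Subread and featureCounts are named in the submitters' processing notes, and their versions and roles are not given in the sources used here. Per the file headers, each deposited table lists 41388 genes by Ensembl identifier with chromosome, start, end, strand and length. The count deposited for each gene is a whole number, unnormalised, per the file headers and values. The CPM deposited by the authors equals the count over the library's summed counts, scaled as its name says, and was checked on the values. The RPKM deposited by the authors equals that CPM per kilobase of the listed length, also checked on the values. The deposited CPM and RPKM were not used further. Genome build, annotation release and use of strand in counting are not given in the sources used here, so antisense and overlapping genes are uncertain.

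Identifiers were matched to GENCODE mouse release M21 for symbols, and 40340 matched. Of these, 76.1% had the same start and end in the files and 99.9% overlapped the annotated gene on the same chromosome, and 174 identifiers lie on patch sequences named in GRCm38 style. Coordinates are printed as the count tables give them. No sequence outside the listed genes entered library sizes. Summed counts ranged from 23047723 to 29078765 per library. Intervals for shares are 95% Wilson intervals, and ratios of genes with 1 to 3 counts over the control group carry exact 95% counting intervals. A gene with 0 control counts was set against a floor of 3 counts over the group.

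Stimulated libraries were compared with controls by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (limma 3.58.1) on the deposited counts, with genes kept by filterByExpr, TMM scaling, robust estimation and treatment as the only term. P-values were adjusted by Benjamini-Hochberg over the 13838 genes tested, with a threshold of 0.05, and for each list also over the list alone. CPM in the text are scaled by TMM. The common biological coefficient of variation was 18.4%. Genes near Il22 were those within 500 kb by the listed coordinates. Reads that Il22 and Iltifb could share were gauged from stretches of 50, 75 and 100 bases found in the exons of both.

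There were 26 gene lists with 556 distinct members, 23 of them in more than 1 list, written from textbook knowledge: effector cytokines, transcription factors and surface receptors of ILC3, NF-kB, STAT3, AP-1, chemokine, glycolysis, cholesterol, amino acid stress, G1/S, G2/M, interferon, AhR, MHC class II, type 1 ILC, type 2 ILC, T cell, B cell, myeloid, stromal, erythroid and epithelial, ribosomal protein, mitochondrial, apoptosis and reference genes. Each list was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Camera called 13 lists, 10 higher and 3 lower. None held with an estimated correlation, where 1 list, that of NF-kB, had an unadjusted p under 0.05 (0.0394), and fry called 11. Camera with an estimated correlation had far less power here, as the simulation below shows. A list that did not pass there may still have changed. Fry tests whether a list moves on balance 1 way, not whether it differs from other genes.

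Genes to be named were chosen by a rule. It took every tested member of the effector cytokine, transcription factor and receptor lists, and the 10 highest and 10 lowest fold changes among genes past the threshold with a mean of at least 5 CPM, both stimulated libraries on the same side of both controls, and a symbol that is not a predicted or clone name. It also took, of each other list, the 3 members past the threshold with the smallest adjusted p and the 2 most abundant members not past it, and all annotated genes within 500 kb of Il22. The rule took 190 genes, 126 past the threshold and 64 not, and a few of them are not reported here. The lists, the rule, the tests and the alternatives were chosen before the data were examined, except for a correction for gene length and GC content and the gene groups described as chosen later under the additional observations.

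Alternatives were other scalings (DESeq2 size factors, upper quartile, total count, and TMM without mitochondrial, ribosomal protein, histone, ribosomal RNA and small RNA genes), other filters (none beyond 1 count, 1 CPM in 2 libraries, 10 counts in both libraries of a group), DESeq2 1.42.0, limma-voom, edgeR's glmTreat against a log2 fold of 1, estimation without robustness, an adjusted p of 0.01, a block for the kind of title, and each library left out in turn. The correction removed a loess trend with gene length and GC content (span 0.3) in each library. With 4 libraries, the fit with a block leaves almost no residual spread of a gene's own. Its very small p-values rest mainly on spread borrowed across genes, not on more replicates.

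The tests were tested on simulated data for the stimulated against control comparison, with counts drawn for 13838 genes from the means and depths of these libraries and 50 genes changed at each fold. The edgeR test recovered 6% of genes changed by a fold of 1.5, 54% at 2, 96% at 4 and 96% at 8. It called 0.11% of unchanged genes. Far fewer genes were changed there than the 4950 called in the data, which makes the adjustment stricter. These rates of the edgeR test therefore do not carry over to the data. Of 100 unchanged lists among 13535 genes, 7% had p under 0.05 with camera at the preset correlation, 0% with the estimated correlation and 7% with fry. A list of genes all changed by a fold of 2 had unadjusted p of 6.44e-45, 0.00989 and 0.0095 in the same order. Simulated genes were drawn independently, so these rates do not cover lists whose members move together. In the data the estimated correlation was 0.387 for ribosomal protein, 0.421 for cholesterol and -0.004 for NF-kB genes, against the preset 0.01.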

Results

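Gene expression was measured by RNA-seq in Mnk3, a mouse cell line that resembles group 3 innate lymphoid cells (ILC3), the tissue lymphocytes known for making IL-22 and IL-17. Cells were left untreated or were stimulated with IL-1b and IL-23, the myeloid cytokines that activate ILC3, at 10 ng/ml each for about 16 h. Libraries were made from total RNA after depletion of ribosomal RNA. There were 4 libraries, 2 of untreated cells (control 1 and 2) and 2 of stimulated cells (stimulated 1 and 2). In each group the library numbered 1 here carries rep1 in its title, and the library numbered 2 carries no number. Summed gene counts were 29078765 in control 1, 28516816 in control 2, 26723058 in stimulated 1 and 23047723 in stimulated 2. Levels are given as CPM, counts scaled for library size, as mean ± SD with n = 2 per group. Changes are log2 fold changes of stimulated over control ± SE. The SE is the absolute change divided by the square root of its F statistic in the edgeR test. It is an approximation, and for steep changes with few counts in 1 group it can fall below the counting error. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

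IL-1b and IL-23 changed the expression of 35.8% of the genes tested. Increases and decreases were nearly equal in number, a balance that TMM scaling favours because it centres the changes (median -0.016). Of the called genes 48.8% were higher, and 40.9% with total-count scaling. A shift shared by all genes could not be seen in these counts. Of 13838 genes tested, 2417 were higher and 2533 lower in stimulated cells at an edgeR adjusted p under 0.05, and 8888 did not pass. Changes of at least 1 on the log2 scale were seen for 1069 of the higher genes, and 1481 of the lower genes had changes of -1 or below. Changes of 3 or more were seen for 179 higher genes, and 149 lower genes reached -3 or below. For all 4950 genes that passed, both stimulated libraries lay on the same side of both controls, as they did for 70.7% of all tested genes against 33.3% by chance. Without stimulated 1 the counts were 1593 higher and 1665 lower. Expression across genes correlated at a Pearson r of 0.986 between the controls, 0.985 between the stimulated libraries and 0.925 to 0.942 between groups, where genes are not independent replicates. Differences between libraries of a group still exceeded counting error, with a chi-square of 70.6 per degree of freedom for the controls and 40.6 for the stimulated libraries.

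The 10 steepest increases among named genes included the cytokine genes Il6, Il22, Iltifb and Ifng. Lcn2, an iron-sequestering antimicrobial protein, rose from 1 count in the 2 controls together to 1129 counts, a ratio of 1390 with a 95% counting interval of 250 to 55100. Il6 rose from 1 to 618 counts (ratio 763, interval 136 to 30200) and Fas, a death receptor, from 1 to 518 counts (ratio 640, interval 114 to 25300). Il22 and its copy Iltifb rose by 8.81 ± 0.46 and 8.93 ± 0.96, and Ifng by 8.75 ± 0.26. Fscn1, an actin-bundling protein, rose by 9.27 ± 0.53 from 0.135 ± 0.00277 to 86.2 ± 38.8 CPM (edgeR adjusted p = 0.000359). Lum, an extracellular matrix proteoglycan, rose by 9.09 ± 0.98 to 57.3 ± 37.8 CPM (edgeR adjusted p = 0.00608), a call that ended without control 1 (0.159, change 10.52) and without control 2 (0.182, change 8.39), and the change was 8.18 without stimulated 1 (0.0756 with all libraries and no low-count filter). Urah rose from 1 to 507 counts (ratio 626, interval 112 to 24800) and Scarf2, a scavenger receptor family member, from 3 to 1157 counts (ratio 476, interval 163 to 2310). These 10 genes had the highest fold changes among genes that passed, had a mean of at least 5 CPM and carried an established symbol. With so few control counts the fitted changes depended on the control left out: Lcn2 gave 12.23 without control 1 and 9.27 without control 2, Il6 11.37 and 8.40, Urah 11.09 and 8.12, and Fas 8.09 and 11.12. Intervals and floors cover counting error only.

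The steepest decreases included receptor genes. Tek, the angiopoietin receptor TIE2, fell from 20.7 ± 2.62 to 0.189 ± 0.0428 CPM, a log2 change of -6.75 ± 0.31 (edgeR adjusted p = 0.000134). Cnr2, the cannabinoid receptor of immune cells, fell from 51.0 ± 3.59 to 2.37 ± 0.11 CPM (-4.42 ± 0.18). Rapsn, a scaffold of acetylcholine receptor clusters, changed by -5.72 ± 0.31, Fam189a1 by -5.61 ± 0.29, Zan by -5.47 ± 0.25 and Morc1 by -4.48 ± 0.17. The tetraspanin Tspan32 changed by -4.97 ± 0.53, and by -4.35 without stimulated 1 and -5.96 without stimulated 2. Tmem273 changed by -4.76 ± 0.41 and Ldhd, a mitochondrial lactate dehydrogenase, by -4.53 ± 0.48, and without stimulated 1 both changed by -5.37. Apol9a, an interferon-inducible apolipoprotein gene, changed by -4.44 ± 0.39 from 95.2 ± 17.9 CPM, and by -5.05 without stimulated 2. Apol9a has close relatives in the genome, and reads could be shared among them.

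The cytokine output of the cells was reshaped, with Il22 and Il17f becoming abundant transcripts. Il22, the gene named in the series title and known for its barrier-protective cytokine, rose from 2.72 ± 0.706 to 1225 ± 520 CPM, a fold of 449 (edgeR adjusted p = 0.000272). Its counts were 97 and 65 in controls 1 and 2 and 40235 and 19574 in stimulated 1 and 2. Il17f, a neutrophil-recruiting cytokine, rose by 7.71 ± 0.37 from 11.4 ± 0.909 to 2383 ± 929 CPM (edgeR adjusted p = 0.00017). Its relative Il17a rose from 2 to 611 counts, a ratio of 377 with an interval of 104 to 3120, and its fitted change was 11.34 without control 1 and 7.46 without control 2. The interferon gamma gene Ifng rose from 0.168 ± 0.0442 to 74.4 ± 9.16 CPM, a fold of 430 (edgeR adjusted p = 0.000103). Among growth factors and ligands, Csf2, which encodes GM-CSF, rose by 4.56 ± 0.41, Csf1 by 3.15 ± 0.29 and Tnfsf4, the ligand of OX40, by 5.74 ± 0.60 (4.95 without stimulated 2). Il9 went from 0 to 41 counts, at least 16.9-fold higher against a floor of 3 counts over the control group. The lymphotoxin genes, Tnf and Tnfsf11 moved the other way. Ltb, which encodes the membrane partner of lymphotoxin alpha and is highly expressed by lymphoid tissue inducer cells, fell from 1138 ± 89.6 to 135 ± 64.8 CPM (-3.08 ± 0.36, edgeR adjusted p = 0.00246). Tnfsf11, the RANK ligand gene, changed by -1.10 ± 0.16, Tnf by -1.05 ± 0.19 and Lta by -0.76 ± 0.17.

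**Figure D1:**
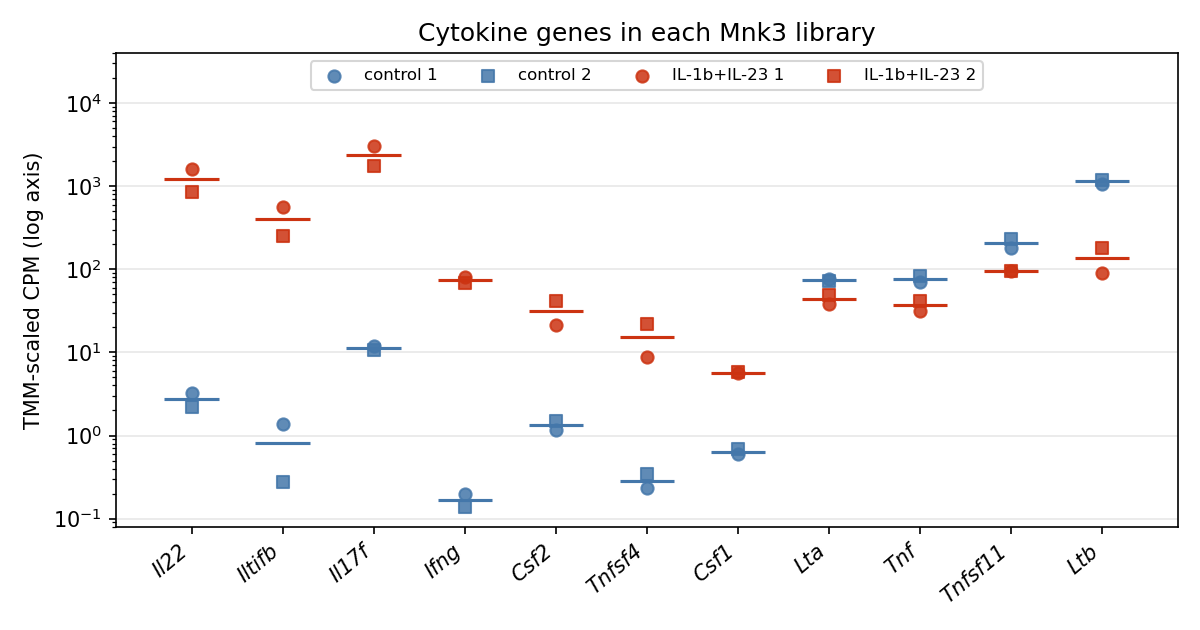
TMM-scaled CPM on a log axis of 11 cytokine genes in each of the 4 libraries, with controls in blue, stimulated libraries in red, and horizontal bars at the group means of 2 libraries. Il22 moves from a mean of 2.72 to 1225 CPM and Ltb from 1138 to 135 CPM.

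Of the 16 tested members of the effector cytokine list, 10 rose, 5 fell and 1 did not pass, and the counts adjusted over the list alone were also 10 and 5. The median change was 3.86, or 3.61 with Il9 at its bound. The list stood above other genes in camera (adjusted p = 0.0127), with an adjusted p = 0.408 with an estimated correlation. Areg, which encodes amphiregulin, had 0.55 ± 0.49 (edgeR adjusted p = 0.426). Without stimulated 1, 8 members rose and 3 fell. Calls of single members ended for Il2 (2.66 ± 0.62; 0.0854 without control 1, 0.0946 without stimulated 1 and 0.0501 in DESeq2) and Lta (0.07 without stimulated 1). Hbegf (-0.74 ± 0.18, edgeR adjusted p = 0.0191) lost its call without any 1 of the 4 libraries, at 0.0506 and 0.0802 without controls 1 and 2 and 0.0733 and 0.0877 without stimulated 1 and 2.

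The region around Il22 was examined because the series concerns the regulation of this gene in cis, and the question was whether its neighbours changed with it. In the coordinates of the count tables, Il22 lies on chromosome 10 from 118204942 to 118210047 on the plus strand, Iltifb from 118289629 to 118295038 on the minus strand and Ifng from 118441047 to 118445892 on the plus strand. These 3 cytokine genes rose by 8.81 ± 0.46, 8.93 ± 0.96 and 8.75 ± 0.26. The other tested neighbours within 500 kb moved by less than 1 on the log2 scale. Mdm1 rose by 0.72 ± 0.18 (edgeR adjusted p = 0.0233), Nup107, a nuclear pore subunit, by 0.65 ± 0.14 (0.0132) and Mdm2, the ubiquitin ligase of p53, by 0.59 ± 0.14 (0.0188). Slc35e3 and Rap1b had -0.40 ± 0.27 and 0.39 ± 0.29 and did not pass. The count tables list 14 genes within 500 kb, 6 of them with no match in the annotation. Of the other 8, all tested, 6 rose, and 6 rose when adjusted over these genes alone. Within 1 Mb they list 29 genes, 13 tested and 7 higher. The counts of both windows include Il22 itself and Iltifb, whose reads cannot be fully separated from those of Il22. Over all genes, 2417 of 13838 tested were higher. The calls of the smaller changes ended in some fits with 1 library left out, where fewer samples enter the test, while their directions stayed. Mdm1 changed by 0.52 without control 1 and 0.63 without stimulated 2. Mdm2 changed by 0.48 without control 1 and 0.54 without stimulated 1, and Nup107 by 0.53 without stimulated 1. With total-count scaling Mdm1 had an edgeR adjusted p = 0.0513.

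**Figure D2:**
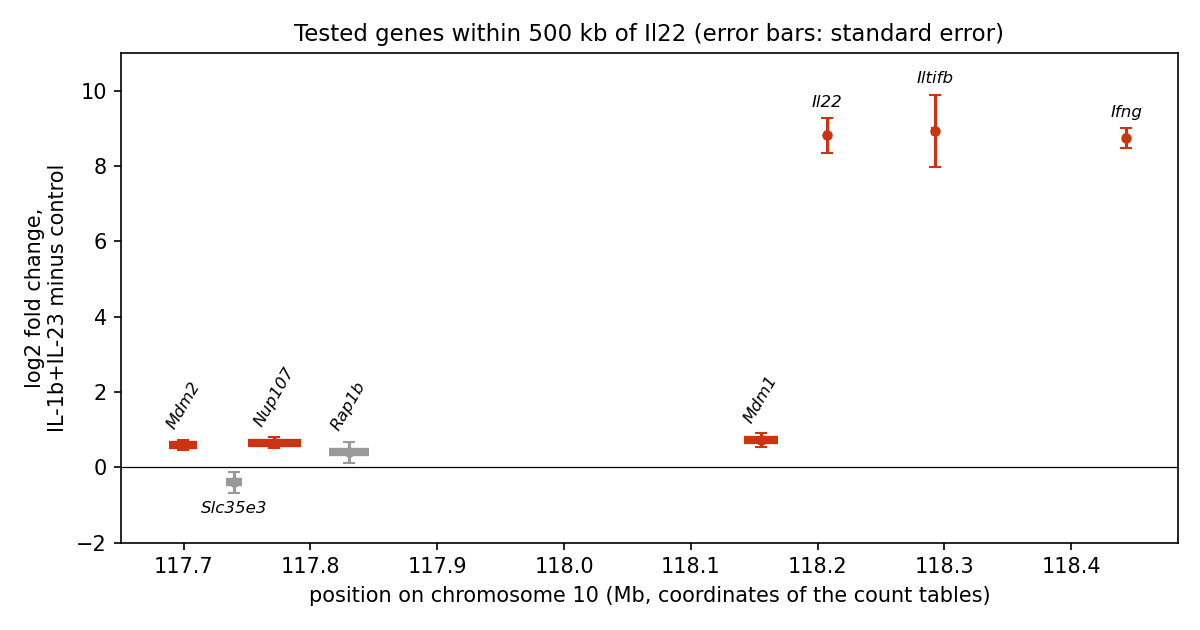
Log2 fold change of stimulated over control, with standard errors, of the 8 tested genes within 500 kb of Il22 against position on chromosome 10 in Mb, red where the gene passed the test and grey where it did not. Il22, Iltifb and Ifng lie near 8.8 and the other genes between -0.40 and 0.72.

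Il22 and Iltifb, a near-identical copy, cannot be fully separated in these counts. Of the 50-base stretches of Il22 exons, 41.0% also occur in Iltifb, and 20.4% of the 100-base stretches do. How the authors' counting treated reads that match both genes is not given in the sources used here, so the split between these 2 genes is uncertain. Iltifb counts were 41 and 8 in the controls and 13987 and 5822 in the stimulated libraries (edgeR adjusted p = 0.0085). Its call ended without control 2 (0.0528, change 8.21), stimulated 1 (0.0639, change 8.27) or stimulated 2 (0.0516), its change was 10.50 without control 1, and its adjusted p was 0.0751 with no low-count filter.

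Transcription factors of ILC3 were mostly lower after stimulation, with falls in 13 of 22. Rora, a nuclear receptor gene of innate lymphoid cells, fell from 1003 ± 151 to 270 ± 77.2 CPM (-1.89 ± 0.24, edgeR adjusted p = 0.00188), and Maf, a regulator of lymphocyte cytokine genes, changed by -1.44 ± 0.15. Ikzf2, which encodes Helios, had the steepest fall of the list at -3.40 ± 0.32. Next was Bach2 at -2.27 ± 0.47, from a low level of 1.43 ± 0.291 CPM. Zbtb16, which encodes PLZF, changed by -1.59 ± 0.25, Tbx21, which encodes T-bet, by -1.33 ± 0.20, Bcl6 by -1.33 ± 0.19, Gata3 by -1.12 ± 0.24 and Runx1 by -0.97 ± 0.16. Stat3, which transmits the IL-23 signal, rose from 222 ± 7.28 to 753 ± 124 CPM (1.76 ± 0.17, edgeR adjusted p = 0.000748). Id3, an inhibitor of E proteins, rose by 3.13 ± 0.39 from a low level of 0.321 ± 0.126 CPM. Ahr, the aryl hydrocarbon receptor gene required by ILC3, had 98.7 ± 11.6 and 98.8 ± 5.37 CPM (0.00 ± 0.15, edgeR adjusted p = 0.994). Tcf7 had -1.58 ± 0.55 (0.104, with 0.0349 without robust estimation and 4e-42 with a block for the kind of title). The value with the block rests mainly on spread borrowed from other genes. Ikzf3 had -0.19 ± 0.15, Runx3 0.17 ± 0.15 (0.0429 after correction for length and GC content) and Hif1a 0.09 ± 0.19. None of these 4 passed in the main test.

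Of 22 tested transcription factors, 4 rose, 13 fell and 5 did not pass, with the same 4 and 13 adjusted over the list alone. The median change was -0.88 and the list stood below other genes in camera (adjusted p = 0.0127), with an adjusted p = 0.434 with an estimated correlation. Smaller calls ended without single libraries. Id2 (0.60 ± 0.15) had 0.0862 without control 1 and 0.0704 without stimulated 2, Nfil3 (1.04 ± 0.22) 0.0556 without stimulated 1 and Runx2 (-0.78 ± 0.20) 0.106 without stimulated 1 and 0.0645 after correction for length and GC content. Ikzf1 (-0.61 ± 0.15) had 0.0775 without control 2, 0.0658 without stimulated 1 and 0.0813 without stimulated 2. Tox (-0.74 ± 0.16) had 0.0707 without control 1, 0.0605 without stimulated 1 and 0.051 without stimulated 2.

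Receptor genes for the stimulating cytokines moved in different directions. Il1r1, the signalling receptor of IL-1, fell from 213 ± 3.18 to 25.3 ± 6.85 CPM (-3.07 ± 0.21, edgeR adjusted p = 0.000282), and Il23r fell from 223 ± 5.55 to 109 ± 14.9 CPM (-1.03 ± 0.15, edgeR adjusted p = 0.00304). Il12rb1, the other chain of the IL-23 receptor, rose by 0.90 ± 0.22 (edgeR adjusted p = 0.0216; 0.0578 without control 2, 0.074 without stimulated 1), and Il1rap, the co-receptor of IL-1, had 0.23 ± 0.16 and did not pass. Il1rn, which encodes the IL-1 receptor antagonist, rose from 2 to 282 counts, a ratio of 174 with an interval of 47.8 to 1450. Other ILC3 surface genes also fell: Nrp1 from 444 ± 50.7 to 26.4 ± 5.49 CPM (-4.07 ± 0.21), Kit, the stem cell factor receptor, from 1124 ± 251 to 279 ± 60.5 CPM (-2.01 ± 0.23), and Il17re, a receptor of IL-17C, by 1.77 ± 0.14 on the log2 scale. Among receptors that guide lymphocytes in tissue, Cxcr5 changed by -2.82 ± 0.26, Cxcr4 by -2.02 ± 0.25 and Cxcr6 by -0.87 ± 0.18. Cd4 changed by -2.93 ± 0.35, the C-type lectins Klrb1f and Klrb1b by -2.43 ± 0.21 and -1.80 ± 0.18, and Tnfrsf21 by -1.76 ± 0.34. S1pr1, the receptor used for tissue egress, rose from 2.84 ± 1.01 to 32.3 ± 6.58 CPM (3.51 ± 0.30, edgeR adjusted p = 0.00058). Il2ra, the alpha chain of the IL-2 receptor, rose by 1.55 ± 0.24, Tnfrsf25 by 1.27 ± 0.13 and the activation marker Cd69 by 0.97 ± 0.17. Il7r had the wide value of -3.08 ± 0.79 and did not pass in the main test (edgeR adjusted p = 0.0654). It did pass in DESeq2 (0.00175), in limma-voom (0.0429), with upper quartile (0.0411) or total-count scaling (0.0322) and with the 1 CPM filter (0.0461). Il7r also passed without robust estimation (0.00966), after correction for length and GC content (0.0493) and with a block for the kind of title (8.6e-100). The titles state no such pairing, and the p-value with the block rests mainly on spread borrowed from other genes. Others that did not pass were Il2rb at 0.01 ± 0.20, Il2rg at -0.28 ± 0.14, Thy1 at -0.11 ± 0.16, Ccr6 at -0.20 ± 0.19 and Ncr1 at -0.37 ± 0.49. Further members that did not pass were Ccr7 at 0.02 ± 0.27, Ccr9 at -0.75 ± 0.69, Ctla4 at -0.50 ± 0.53, Icos at -0.24 ± 0.22, Il18r1 at 0.55 ± 0.25 and Il18rap at 0.39 ± 0.16.

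Of 33 tested receptors, 6 rose, 14 fell and 13 did not pass, with 6 and 15 adjusted over the list alone. The median change was -0.50 and the list stood below other genes in camera (adjusted p = 0.0225), with an adjusted p = 0.408 with an estimated correlation. The call of Il1rn ended without control 1 (0.0594) or control 2 (0.0704), and its change was 6.06 without stimulated 1 and 7.89 without stimulated 2. Calls also ended for Itga4 (-1.88 ± 0.49; 0.0757 without control 2, 0.0733 without stimulated 1, and a change of -2.62 without stimulated 2) and Itgb7 (-0.82 ± 0.17; 0.0513 without stimulated 2).

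Targets of NF-kB and STAT3, the pathways downstream of IL-1 and IL-23, rose in part, with increases in 16 of 37 and 17 of 25 tested members. Among NF-kB targets, the pathway engaged by the IL-1 receptor, Gadd45b rose by 3.98 ± 0.17 (edgeR adjusted p = 0.000134) and Tnfrsf9, the gene of the costimulatory receptor 4-1BB, by 3.42 ± 0.20 from 91.4 ± 2.02 to 977 ± 202 CPM. The NF-kB subunit genes Nfkb1 and Nfkb2 had -0.24 ± 0.14 and -0.43 ± 0.15 and did not pass, though Nfkb2 did in DESeq2 (0.0226) and with upper quartile (0.0408) or total-count scaling (0.0361). Among targets of STAT3 and feedback genes of JAK-STAT signalling, the kinase gene Pim2 rose by 5.81 ± 0.22 from 2.72 ± 0.325 to 153 ± 29.2 CPM, and the feedback inhibitors Cish and Socs1 by 3.86 ± 0.23 and 3.42 ± 0.19. Mcl1, a survival factor, had 0.29 ± 0.16 and did not pass. Of 37 NF-kB genes, 16 rose, 1 fell and 20 did not pass, with 18 and 2 adjusted over the list alone and a median of 0.57. This list stood above other genes in camera (adjusted p = 0.000143), with an adjusted p = 0.408 with an estimated correlation. Without stimulated 2 the number of its members that fell was 2, and without stimulated 1 the lower member did not pass. Of 25 STAT3 genes, 17 rose, 4 fell and 4 did not pass, with 18 and 4 adjusted over the list alone and a median of 1.58. Its camera adjusted p was 1.75e-05, and its adjusted p = 0.408 with an estimated correlation.

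AP-1 and BATF family genes moved both ways. Batf, a cofactor of lymphocyte cytokine genes, rose by 2.41 ± 0.18 and Jun by 2.25 ± 0.22, while the small Maf gene Maff changed by -1.71 ± 0.16. Irf4 had counts of 24 and 0 in the controls and 1836 and 442 in the stimulated libraries, a change of 6.82 ± 1.55 that did not pass in the main test (edgeR adjusted p = 0.0604). Irf4 did pass in DESeq2 (0.025), with upper quartile (0.0332) or total-count scaling (0.0234), with the 1 CPM filter (0.0398) and without robust estimation (0.00554). It also passed with a block for the kind of title (2.3e-145), a pairing that the titles do not state. That small p-value rests mainly on spread borrowed from other genes, not on replication of Irf4. Mafk had -0.59 ± 0.25 and did not pass, though it did with no low-count filter (0.00235). Of 22 tested members, 9 rose, 7 fell and 6 did not pass, with 11 and 8 adjusted over the list alone, a median of 0.50 and a camera adjusted p of 0.447. Among chemokines, Cxcl9, a ligand of CXCR3, rose by 6.58 ± 0.45, Cxcl10, which shares that receptor, by 3.71 ± 0.23, and Ccl20, the ligand of CCR6, from 2 to 51 counts, a ratio of 31.5 with an interval of 8.28 to 267 (fitted change 7.77 without control 1 and 3.90 without control 2). Ccl1 had 2.55 ± 0.97 (0.126, and 0.047 without robust estimation) and Ccl5 -0.58 ± 0.30, and neither passed in the main test. Of 8 tested chemokines, 4 rose, 1 fell and 3 did not pass, with 4 and 1 adjusted over the list alone and a median of 3.12. The chemokine list had a camera adjusted p of 0.0654, which passed at 0.026 without control 1, 0.000178 without stimulated 1 and 0.0433 without stimulated 2. Without either control 3 chemokines rose and the lower member did not pass, and without stimulated 1 the numbers were 6 and 1.

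**Figure D3:**
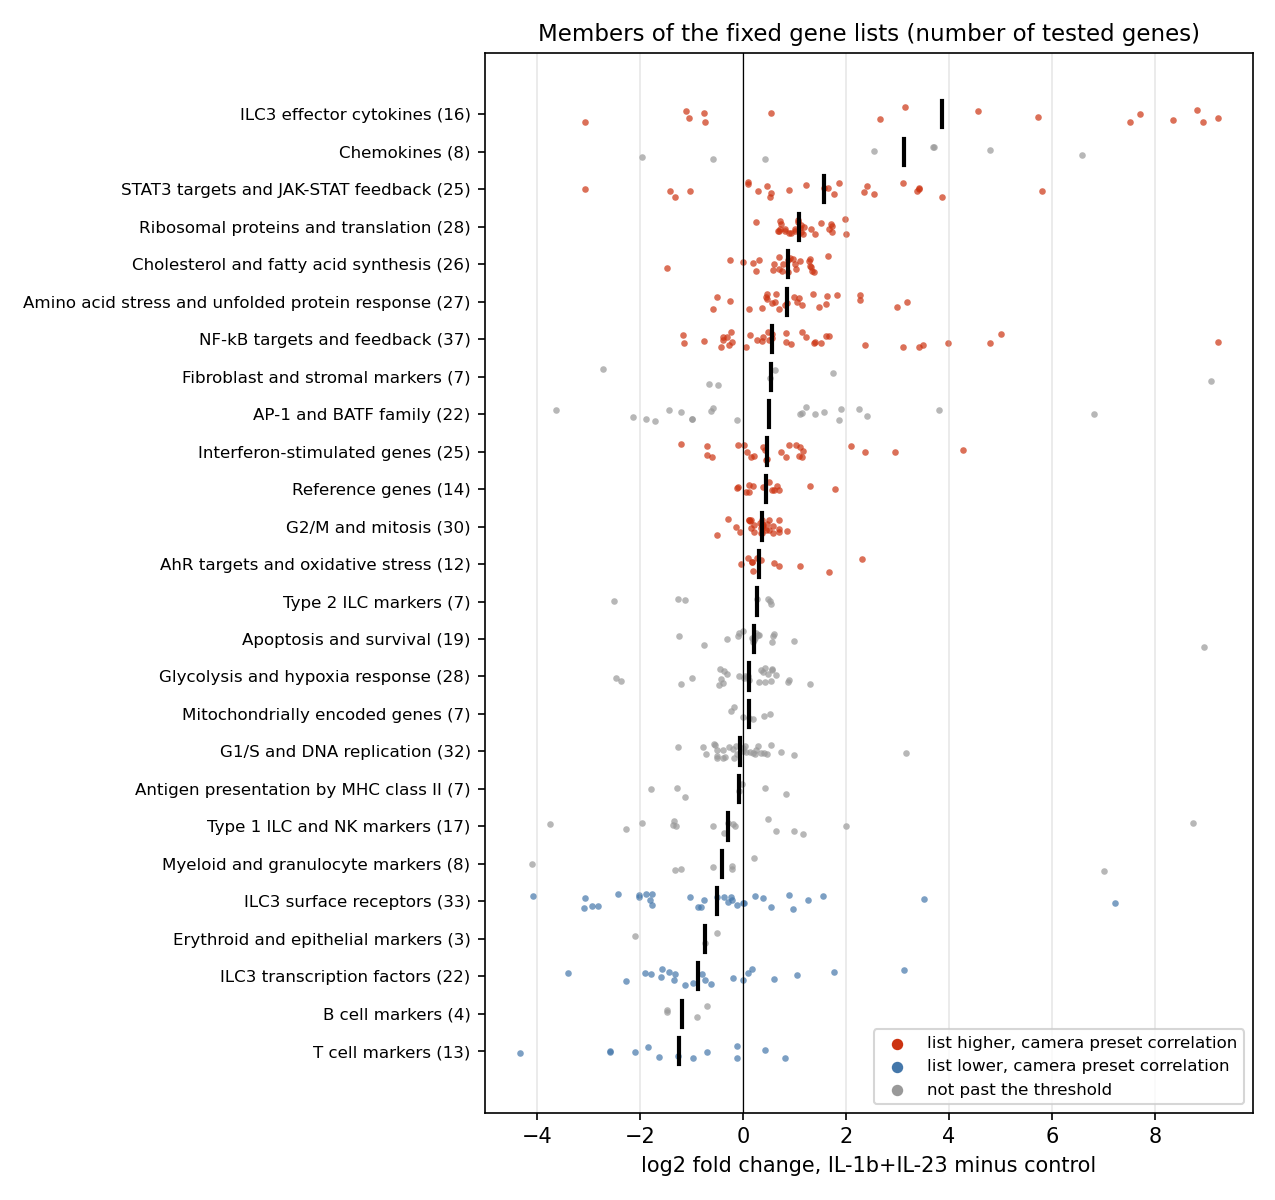
Log2 fold change of stimulated over control for each tested member of the 26 fixed gene lists, with black bars at list medians, and red or blue where the list passed camera with a preset correlation. Medians run from -1.25 for T cell markers to 3.86 for effector cytokines, and 0 lists passed with an estimated correlation.

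Interferon-stimulated genes rose in part, with increases in 12 of 25. Gbp3, an interferon-inducible GTPase, rose by 4.27 ± 0.25 from 4.32 ± 0.945 to 83.1 ± 18.4 CPM (edgeR adjusted p = 0.00023) and Gbp2 by 2.37 ± 0.23. Bst2 at 0.38 ± 0.17 and Parp14 at 0.46 ± 0.16 did not pass, though Parp14 did in DESeq2 (0.0378), with DESeq2 size factors (0.0497), with no low-count filter (0.0227) and after correction for length and GC content (0.0121). Of 25 tested members, 12 rose, 2 fell and 11 did not pass, with 13 and 2 adjusted over the list alone and a median of 0.46. The camera adjusted p was 0.00264, and the adjusted p = 0.408 with an estimated correlation. Without control 1, control 2 or stimulated 2, 1 member fell, and without stimulated 1 no lower member passed. Gbp genes belong to a family of close copies, and reads could be shared among them.

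Few genes of the AhR pathway and of oxidative stress passed the test, 3 of 12. Txnrd1 rose by 0.71 ± 0.14 and its substrate thioredoxin, Txn1, by 1.10 ± 0.28, while Cyp1b1 had 2.32 ± 0.66 (edgeR adjusted p = 0.0729; 0.00948 in DESeq2, 0.0463 with total-count scaling and 0.0168 without robust estimation) and Tiparp -0.04 ± 0.25. The call of Txn1 ended without stimulated 1 (0.0966), as did that of Nqo1, a quinone reductase (1.68 ± 0.54, edgeR adjusted p = 0.0492; 0.12 and 0.137 without controls 1 and 2, and 0.363 at a change of 0.98 without stimulated 1). The Nqo1 call also ended with upper quartile (0.0616) or total-count scaling (0.0676), without robust estimation (0.0526), after correction for length and GC content (0.0617), in DESeq2 (0.133) and in limma-voom (0.0687). Of 12 tested members 3 rose and 9 did not pass, with 2 rising when adjusted over the list alone, and 1 without stimulated 1. The list's median was 0.32 and its camera adjusted p 0.0202, with an adjusted p = 0.496 with an estimated correlation and a camera adjusted p of 0.141 without stimulated 1. Among genes of MHC class II antigen presentation, Ciita, the master regulator of the class, fell by 1.12 ± 0.15 on the log2 scale, and H2-Aa had -1.79 ± 0.46 (edgeR adjusted p = 0.0239) from 0.875 ± 0.018 CPM. Cd74, the invariant chain gene, had -0.07 ± 0.21 and Cd40 0.84 ± 0.32, and neither passed, though Cd40 did in DESeq2 (0.0441) and with no low-count filter (0.0025). Of 7 tested members 2 fell and 5 did not pass, with 2 adjusted over the list alone, a median of -0.07 and a camera adjusted p of 0.554. The call of H2-Aa ended without any 1 library, at 0.0846 and 0.0911 without controls 1 and 2 and 0.125 and 0.0524 without stimulated 1 and 2, and in DESeq2 (0.111). The numbers of members that rose and fell were 0 and 1 without control 1 or stimulated 2, 1 and 2 without control 2, and 1 and 1 without stimulated 1.

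Lists of amino acid stress and unfolded protein response genes and of cholesterol and fatty acid synthesis genes held increases in 18 of 27 and 20 of 26 tested members. Phgdh, the first enzyme of serine synthesis, rose by 3.19 ± 0.17 from 8.66 ± 0.465 to 79.1 ± 9.03 CPM (edgeR adjusted p = 0.00017), Psat1 of the same pathway by 1.83 ± 0.13 and their regulator Atf4 by 1.61 ± 0.15 to 824 ± 37.0 CPM. In the list of amino acid stress and unfolded protein response genes, 18 of 27 rose, 1 fell and 8 did not pass, with 20 and 1 adjusted over the list alone and a median of 0.86. Its camera adjusted p was 3.89e-07, and its adjusted p = 0.408 with an estimated correlation. The protein disulfide isomerase genes Pdia4 and Pdia3 had 0.47 ± 0.15 and 0.56 ± 0.42 and did not pass in the main test. With a block for the kind of title both did (0.000366 and 5.24e-06). Pdia4 stood at 0.0501 there and passed in DESeq2 (0.0155), in limma-voom (0.0449), with DESeq2 size factors (0.0447), with scaling without RNA classes (0.0437) and with no filter (0.0277), the 1 CPM filter (0.0476) or the 10-count filter (0.046). In the cholesterol and fatty acid synthesis list, Fdps, an enzyme of the mevalonate pathway, rose by 1.37 ± 0.17, while the cholesterol exporter gene Abcg1 changed by -1.47 ± 0.14. Srebf2 at 0.32 ± 0.19 and Acly at 0.26 ± 0.19 did not pass. Of 26 members 20 rose, 1 fell and 5 did not pass, with 20 and 1 adjusted over the list alone and a median of 0.88, and the camera adjusted p was 2.68e-06, with an adjusted p = 0.434 with an estimated correlation. The single lower member of the amino acid list did not pass without control 2, stimulated 1 or stimulated 2.

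Genes of ribosomal proteins and translation were higher after stimulation, 21 of 28. Rpl27 rose by 1.99 ± 0.18, Rpl10a by 1.73 ± 0.16 and Rpl3 by 1.68 ± 0.16 (edgeR adjusted p = 0.000738). Rplp1 at 1.18 ± 0.61 and Eef2, the translocation factor, at 0.25 ± 0.22 did not pass. With a block for the kind of title Rplp1 passed (6.04e-20). Of the 28 tested members 21 rose and 7 did not pass, with 23 rising when adjusted over the list alone. The median was 1.09 and the camera adjusted p 7.59e-10, with an adjusted p = 0.408 with an estimated correlation. Ribosomal protein genes have many processed pseudogenes, and reads could be shared with them. Short genes were higher in stimulated libraries in general: the tenth of abundant protein-coding genes with the shortest transcripts (median length 1214 bases) had a median change of 0.44 and the tenth with the longest (10737 bases) -0.18.

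Glycolysis and mitochondrially encoded genes did not move as groups. Pgk1 rose by 1.31 ± 0.20 and Eno1 by 0.87 ± 0.18, whose call ended without stimulated 1 (0.0559), while Bnip3l, a mitophagy receptor gene induced by hypoxia, changed by -1.20 ± 0.20. Pkm and Aldoa, abundant glycolytic genes, had 0.39 ± 0.17 and 0.42 ± 0.17 and did not pass, though both did after correction for length and GC content (0.0493 and 0.0358) and Aldoa in DESeq2 (0.044). Of 28 tested members, 5 rose, 5 fell and 18 did not pass, with 5 and 5 adjusted over the list alone. The list's median was 0.12, its mean -0.05 and its camera direction upward at an adjusted p of 0.617. Without control 1 the counts were 3 and 5, without control 2 or stimulated 2 they were 5 and 2, and without stimulated 1 they were 2 and 1. Of 7 tested mitochondrial genes, edgeR called 0 at an adjusted p under 0.05 and 0 at an unadjusted p under 0.05, also when adjusted over the list alone, as did DESeq2 and limma-voom over all genes, with mt-Co1 at -0.17 ± 0.25 and mt-Nd1 at 0.53 ± 0.34 (adjusted p = 0.015 with no low-count filter). Their median was 0.11 and the camera adjusted p 0.555, which was 0.00292 with 4 members higher without control 1, and 1 member was lower without control 2.

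Cell cycle genes changed in small part, with increases in 6 of 32 G1/S genes and 7 of 30 G2/M genes. For G1/S and DNA replication, Tyms, the thymidylate synthase gene, rose by 0.98 ± 0.14, E2f2 by 0.74 ± 0.13 and Ccnd2, a D-type cyclin gene, by 3.17 ± 0.45 from 0.904 ± 0.505 CPM (3.89 without control 1). The replicative helicase genes Mcm3 and Mcm5 had -0.00 ± 0.15 and -0.38 ± 0.15 and did not pass, though Mcm5 did with upper quartile (0.0472) or total-count scaling (0.0352). Of 32 members, 6 rose, 5 fell and 21 did not pass, with 4 and 4 adjusted over the list alone. The median was -0.06, the mean 0.02 and the camera direction downward at an adjusted p of 0.886. Without control 1 the numbers that rose and fell were 4 and 3, without control 2 they were 3 and 5, without stimulated 1 they were 3 and 3, and without stimulated 2 they were 4 and 2. For G2/M and mitosis, Ube2c rose by 0.86 ± 0.16, Top2a by 0.70 ± 0.17 and the checkpoint kinase gene Bub1b by 0.70 ± 0.18, while Mki67, the proliferation marker, had -0.14 ± 0.23 and Kif11 0.15 ± 0.15. Of 30 members, 7 rose, 1 fell and 22 did not pass, with 5 and 1 adjusted over the list alone, a median of 0.37 and a camera adjusted p of 0.003, or adjusted p = 0.408 with an estimated correlation. Without stimulated 1, 1 of the 30 rose, and the lower member did not pass without any 1 library. The calls of Top2a ended without control 1 (0.111) and stimulated 1 (0.0531), and those of Bub1b without control 2 (0.0607) and stimulated 1 (0.125).

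Among apoptosis and survival genes, Bcl2, the survival factor, fell from 296 ± 48.7 to 125 ± 20.2 CPM (-1.24 ± 0.19, edgeR adjusted p = 0.00314) and Fas rose as above. Bak1, a death effector gene, rose by 0.60 ± 0.13, a call that ended without stimulated 1 (0.0667), and Ccng1 had 0.19 ± 0.26. Of 19 tested members, 4 rose, 2 fell and 13 did not pass, with 4 and 1 adjusted over the list alone, a median of 0.21 and a camera adjusted p of 0.202. Without stimulated 1 the numbers were 1 and 1, and without control 2 they were 4 and 1. The list of reference genes was not level. Tfrc, the transferrin receptor gene, rose by 1.79 ± 0.18, Pgk1 by 1.31 ± 0.20 and Ppia by 0.69 ± 0.14, while B2m at 0.38 ± 0.17 and Rpl13a at 0.51 ± 0.19 did not pass, though both did in DESeq2 (0.0381 and 0.0275), and Rpl13a with no low-count filter (0.0217) and after correction for length and GC content (0.0326). Of 14 reference genes 6 rose and 8 did not pass, with 6 rising when adjusted over the list alone, and 3 without stimulated 1. Their median was 0.44 and the camera adjusted p 0.00957, with an adjusted p = 0.408 with an estimated correlation.

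Markers of other lymphocyte types were mostly lower or did not pass. Among type 1 ILC and NK markers, Ifng rose, while Cxcr3, the receptor of CXCL9 and CXCL10, fell from 38.8 ± 2.46 to 2.89 ± 0.000715 CPM (-3.75 ± 0.18) and Klrb1c, which encodes NK1.1, changed by -1.97 ± 0.17. The granzyme gene Gzmc had -0.28 ± 0.21 at a high level of 903 ± 60.3 CPM in controls, and Il12rb2 had -0.20 ± 0.58. Of 17 tested members 2 rose, 6 fell and 9 did not pass, with 2 and 6 adjusted over the list alone, a median of -0.28, a mean of 0.03 and a downward camera adjusted p of 0.211. Among type 2 ILC markers, Hpgds, a prostaglandin D synthase gene, changed by -2.50 ± 0.17 and Lmo4 by -1.26 ± 0.21, while Klrg1 had 0.52 ± 0.27. Of 7 members 3 fell and 4 did not pass, with 3 adjusted over the list alone, a median of 0.27, a mean of -0.44 and a downward camera adjusted p of 0.397. Without stimulated 2 a member of this list also rose. Among T cell markers, Zap70, a kinase of antigen receptor signalling, fell from 574 ± 17.4 to 161 ± 11.8 CPM (-1.84 ± 0.15), Trbc2 changed by -2.58 ± 0.25 and Lat by -2.10 ± 0.21. Cd28 at -0.69 ± 0.39 (0.00716 with no low-count filter) and Cd3d at -0.12 ± 0.32 did not pass. Of 13 members 6 fell and 7 did not pass, with 7 adjusted over the list alone, a median of -1.25 and a camera adjusted p of 0.00518, or adjusted p = 0.408 with an estimated correlation.

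Markers of B cells and of cell types outside the lymphoid lineage had few tested members. Cd79b, a B cell receptor component, had -1.47 ± 0.39 (edgeR adjusted p = 0.0265) from 1.98 ± 0.683 CPM, a call that ended without control 2 (0.157) or stimulated 1 (0.0985) and in DESeq2 (0.0526), while Cd79a at -1.47 ± 0.59 (0.00762 with no low-count filter) and Fcer2a at -0.69 ± 0.40 did not pass. Of 4 tested B cell markers 1 fell and 3 did not pass, with 1 adjusted over the list alone, a median of -1.18 and a camera adjusted p of 0.161. The numbers of these markers that rose and fell were 1 and 1 without control 1, 1 and 0 without control 2, 0 and 0 without stimulated 1, and 1 and 2 without stimulated 2. Cpa3, a mast cell protease gene, changed by -4.09 ± 0.50 (-3.45 without control 2). Adgre1, the macrophage gene for F4/80, went from 2 to 231 counts, a ratio of 143 with an interval of 39.0 to 1180, and its fitted change was 7.74 without stimulated 1 and 5.54 without stimulated 2. Its call ended without control 1 (0.171, change 10) or control 2 (0.212, change 6.12), and Cd68 at 0.22 ± 0.29 and Fcgr1 at -1.33 ± 1.15 did not pass. Of 8 myeloid markers 1 rose, 1 fell and 6 did not pass, also when adjusted over the list alone, with a median of -0.40 and a camera adjusted p of 0.706. The number that rose was 0 without control 2 and 2 without stimulated 2.

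Among fibroblast and stromal markers, Lum rose as above, Col6a1 rose by 1.76 ± 0.40, a call that ended without stimulated 1 (0.0522), and Col3a1 changed by -2.73 ± 0.50 (-2.11 without stimulated 1 and -3.74 without stimulated 2). Col5a1 at -0.48 ± 0.20 (0.0175 with no low-count filter) and Tagln at -0.65 ± 0.28 did not pass. Of 7 stromal markers 3 rose, 1 fell and 3 did not pass, with 3 and 1 adjusted over the list alone, a median of 0.54 and a camera adjusted p of 0.706. Without control 1 the numbers that rose and fell were 1 and 2, without control 2 or stimulated 1 they were 1 and 1, and without stimulated 2 they were 2 and 1. Krt8, an epithelial keratin gene, changed by -2.10 ± 0.44 from a low level of 1.175 ± 0.262 CPM. Its call ended without control 1 (change -1.86). The erythroid genes Klf1 and Alas2 had -0.74 ± 0.41 and -0.50 ± 0.46 and did not pass. Of 3 tested erythroid and epithelial markers 1 fell and 2 did not pass, with 1 adjusted over the list alone, a median of -0.74 and a camera adjusted p of 0.238.

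Library composition was compared between groups as a sign of RNA quality, as values with no test run. An exact two-sided permutation test of 2 libraries against 2 cannot give a p under 0.33. Ribosomal protein genes took 1.20% and 0.924% of counts in controls 1 and 2 and 1.95% and 1.69% in stimulated 1 and 2. Mitochondrial genes took 0.659% and 0.366% in the controls and 0.453% and 0.485% in the stimulated libraries. Histone genes took 1.24% and 0.508% in the controls and 1.51% and 0.922% in the stimulated libraries, so that the library titled rep1 had the larger share in each group. The small nuclear RNA Rn7sk took 1.20% in control 1, 0.249% in control 2, 0.439% in stimulated 1 and 0.265% in stimulated 2, and other small RNA genes 0.447%, 0.154%, 0.252% and 0.259%. Genes that hold ribosomal RNA or resemble it took 0.495% and 0.502% in the controls and 0.858% and 0.908% in the stimulated libraries. The 20 most abundant genes took 5.84%, 4.76%, 6.29% and 5.87% of counts in the same order. The 95% Wilson intervals of these shares reached at most 0.00959 percentage points to either side.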

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

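The correction for gene length and GC content was chosen after the result was seen, and the other tests below were chosen before. Il22 passed under all 18 alternatives, with changes from 8.30 to 9.22. Of the 126 named genes past the threshold, 98 kept their call in every refit but glmTreat that gave them a value (121 of the 126 had one with the 1 CPM filter), at the threshold of 0.05, 28 lost it without 1 library and 8 of these also under another setting, and all kept their direction. Without control 1 the call of 13 ended, without control 2 that of 12, without stimulated 1 that of 21 and without stimulated 2 that of 8. Of the 64 that did not pass, 10 passed in DESeq2, 9 with no filter and 30 with the replicate block. Most of these block calls are not printed beside the genes above. With 1 library left out, the lone library of its group is assumed to vary like the other group, so fewer samples enter the test. Of all 4950 genes past the threshold, 4650 also passed in DESeq2, 4865 in limma-voom, 4476 after the length and GC correction (which turned the sign of 2), and 3559, 3630, 3126 and 3592 without control 1, control 2, stimulated 1 and stimulated 2. The share of higher genes among those called was 48.8%, and 40.9% to 50.4% over the other scalings, which shifted the median gene by at most -0.091. In the simulation most changes by a fold of 1.5 were not recovered, but far fewer genes were changed there than were called here. That makes the adjustment stricter, so the rate does not carry over to these data. A gene that did not pass may still have changed.

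The numbers of higher and lower genes were 1244 and 1324 at an adjusted p under 0.01, 390 and 527 with glmTreat (also for changes of at least 1 and at most -1), 1593 to 2001 and 1665 to 2035 with 1 library left out (lowest without stimulated 1), 3986 and 4000 with a replicate block for the kind of title, and 4266 higher with that block and the length and GC correction. The block kept 4946 of the 4950 genes. The titles mark only 1 library of each group with rep1 and state no pairing. Deviations of the libraries with like titles correlated at 0.49 across genes, and at 0.655 across genes with at least 100 counts in every library. The main test has no term for this split, so it counts there as spread within the groups. Of the genes near Il22, 3 passed with glmTreat and 3 to 5 with 1 library left out (3 without stimulated 1).

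Chemokines passed with total-count scaling (0.0417), no filter (0.00316), the replicate block (0.00377), the block with the correction (0.00326) and fry (0.0449), and had 0.000178 to 0.0544 with 1 library left out. With no filter type 1 ILC markers passed (0.0377), and the direction turned for myeloid (0.455) and erythroid and epithelial markers (0.877). Effector cytokines had 0.0726 with the 1 CPM filter, which removes low members. AP-1 genes passed with the block (0.00377) and with the block and correction (0.000363). The correction gave 0.0544 for AhR targets and turned mitochondrial genes (0.973). With the block and correction the adjusted p was 0.113 for G2/M, 0.0522 for AhR targets, 0.0674 for reference genes and 0.0395 for type 2 ILC markers, and G1/S turned (0.89). With an estimated correlation 0 lists passed, 1 with an unadjusted p under 0.05. The adjusted p was then 0.408 for effector cytokines, receptors, NF-kB, STAT3, amino acid stress, G2/M, interferon, T cell, ribosomal and reference genes, 0.434 for transcription factors and cholesterol genes and 0.496 for AhR targets. In fry transcription factors (0.06), cholesterol (0.0636), AhR (0.135) and reference genes (0.06) did not pass, MHC class II did (0.0465) and G1/S turned (0.555). With 1 library left out, the adjusted p ran from 0.0031 to 0.141 for AhR targets (highest without stimulated 1), 0.00292 to 0.6 for mitochondrial genes (lowest without control 1), 0.342 to 0.951 for glycolysis, 0.83 to 0.981 for G1/S and 0.531 to 0.981 for myeloid markers, with turned directions in the last 4. The group difference in ribosomal RNA look-alikes was 0 percentage points as rounded when only genes with an established symbol were counted. These hold 20 to 66 such counts per library. That setting removes nearly all of the look-alikes by their names, so it does not bear on the difference among all genes. The cause of the differences in this paragraph was not tested.

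Signs turned for 20 of the 64 named genes that did not pass, with 47 values. With upper quartile scaling these were Ahr (-0.048), Ccr7 (-0.031) and Il2rb (-0.045), and with total counts Ahr (-0.088), Ccr7 (-0.071) and Il2rb (-0.087). The 1 CPM filter turned Ahr (-0.007) and Il2rb (-0.001), the block Il2rb (-0.008) and limma-voom Il2rb (-0.009). Mcm3 turned with DESeq2 size factors (0.018), scaling without RNA classes (0.011), no filter (0), the 10-count filter (0.005) and DESeq2 (0.018). The correction turned Ccr7 (-0.002), Mcm3 (0.077) and Mki67 (0.064), and with the block Mcm3 (0.077) and Mki67 (0.038). With 1 library left out the ranges were Tiparp -0.434 to 0.293, Cd74 -0.34 to 0.264, Ccng1 -0.157 to 0.63, Ahr -0.115 to 0.126, Ccr6 -0.475 to 0.05, Ccr7 -0.336 to 0.478, Ccr9 -1.381 to 0.291, Ctla4 -1.565 to 0.115, Hif1a -0.138 to 0.358, Icos -0.504 to 0.087 and Il2rb -0.253 to 0.258. They were Ncr1 -1.17 to 0.153, Mcm3 -0.063 to 0.084, Mki67 -0.463 to 0.147, mt-Co1 -0.492 to 0.232, Fcgr1 -3.174 to 0.278, Eef2 -0.052 to 0.518, Cd28 -1.168 to 0.028, Cd3d -0.49 to 0.389 and Il12rb2 -0.927 to 0.393.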

Other observations

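The gene groups and single genes of this part, and the tests of low-level cytotoxic markers, library preparation, pseudogenes, stromal transcripts and interferon gamma, were chosen only after the result was seen. Ribosome biogenesis genes rose with the ribosomal proteins. Of 35 tested factors 33 rose and 2 did not pass, with a median change of 1.55 (95% bootstrap interval 1.38 to 1.64). Bootstrap intervals in this part resample the genes of a group, which are not independent replicates. They do not measure the spread between libraries. Npm1, a nucleolar chaperone, rose by 1.79, the snoRNP genes Nop58 and Dkc1 by 1.86 and 1.88 and Nop16 by 2.17, while Fbl at 1.21 (edgeR adjusted p = 0.0512) and Pes1 at 0.33 did not pass. Camera gave p = 6.25e-20 against all genes, and p = 0.0861 with an estimated correlation. Further abundant genes that rose were Ly6a, from 495 ± 148 to 3731 ± 927 CPM (n = 2 each, 2.91 ± 0.29), Stat5a, a transducer of IL-2 family signals, from 74.8 to 709 CPM (3.24 ± 0.20), and the transcription factor gene Zeb2 (3.76 ± 0.15). Sdc1, which encodes syndecan-1, fell from 473 ± 126 to 36.0 ± 12.4 CPM (-3.72 ± 0.32), and Smad3, a transducer of TGF-beta signals, changed by -2.12.

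Genes known to be induced by interferon gamma rose widely. Of 30 tested members of a list of such genes 28 rose, 1 fell and 1 did not pass, with a median change of 2.04 (95% bootstrap interval 1.45 to 2.56). The GTPase genes Igtp and Iigp1 rose by 3.14 and 8.28, the peptide transporter gene Tap1 by 1.80, its regulator Nlrc5 by 2.33 and the immunoproteasome gene Psmb9 by 1.44. Ciita fell by 1.12 on the log2 scale and Batf2 did not pass. In a list of type I interferon genes 4 of 25 rose (Isg15, Usp18, Slfn8 and Xaf1), 4 fell (Ifit2, Oasl2, Ddx60 and Epsti1) and 17 did not pass, with a median of 0.12 (-0.34 to 0.41). A candidate explanation is a response to the interferon gamma that the cells' own Ifng would give. The gamma list stood above the type I list in camera (p = 1.1e-09), with p = 0.0564 with an estimated correlation, so the hypothesis stays open. The test is not independent of the report, since the lists include Gbp2, Gbp3, Cxcl9, Socs1 and other genes seen there. GTPase genes of these families have close copies that could share reads.

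Libraries split by the kind of title as well as by treatment, with 1082 genes higher and 1096 lower in the rep1 libraries by the block term of edgeR. The granzyme gene Gzma had 193 and 0 counts in controls 1 and 2 and 320 and 0 in stimulated 1 and 2, and Prf1, the perforin gene, 178 and 7, and 338 and 8, while the median difference of 56 histone genes was 1.80 in controls and 1.16 in stimulated cells, with 56 and 54 of them higher in the rep1 library. Cytotoxic NK or T cells in the rep1 libraries would bring their other transcripts. The 14 other markers differed by a median of at most 0.35, and 9 markers of low level by at most 0.42. Both medians lay below 1 by more than their intervals. Yet the granzyme genes Gzmg, Gzmf and Gzmd were higher in rep1 libraries by 11.621, 8.497 and 5.514 in the block term. Cd3d, Nkg7 and Gzmb were higher there by 0.64, 0.42 and 0.44. The markers Ctsw, Cst7 and Gzmb had 388.34, 222.74 and 146.95 CPM in control 2, levels that few added cells would hardly move. The medians therefore cannot exclude a small share of cytotoxic cells, which stays open. More cells in S phase were argued against by the G1/S genes, whose larger median difference was 0, while a preparation that keeps short RNA in both rep1 libraries was argued against by small RNA genes, whose median difference was 0.30 (0.22 to 0.43) in controls but -0.34 (-0.44 to -0.22) in stimulated cells. Such a preparation stays open for control 1 alone, with Rn7sk higher in both rep1 libraries. A preparation that keeps longer RNA without a poly(A) tail cannot be judged from small RNA genes and also stays open. A different culture or passage of the line stays open and untested.

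Higher ribosomal protein genes could come from the trend of change with gene length, but after correction for length and GC content the median of the list was 1.05 (95% bootstrap interval 0.85 to 1.26) against 1.09 (0.91 to 1.25) before, with 21 of 28 members past the threshold both before and after, not checked to be the same ones, and a camera adjusted p of 5.74e-09. Reads that moved from processed pseudogenes to the genes would lower pseudogene counts as gene counts rise. The counts of 256 ribosomal protein pseudogenes rose instead, by 0.54 on the log2 scale between rep1 libraries and 0.74 between unnumbered ones. Shared reads would also make both rise together, so these counts cannot decide whether reads were shared. An increase of these transcripts with stimulation is a hypothesis, and it rests on the same data, with an adjusted p = 0.408 for the list with an estimated correlation. Lum, the matrix gene that rose in stimulated cells, may come from stromal cells, but Col1a1, Col1a2, Sparc, Dcn and Fn1, abundant in such cells, reached at most 0.86% of its level in a stimulated library. Col1a1 had 7, 3, 6 and 6 counts in controls 1 and 2 and stimulated 1 and 2, and Col3a1 fell from 203 and 247 counts to 14 and 40. The call of Lum ended without control 1 (0.159) or control 2 (0.182), and expression of Lum by Mnk3 cells stays a hypothesis.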
